A study of Mus musculus with 6 samples.

How the data were processed

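Total RNA from brown adipose tissue of 6 mouse samples, 3 control and 3 YY1bKO, was extracted with Trizol and turned into biotin-labelled cRNA from 6 ug of RNA for Affymetrix expression arrays, per the labels' protocols. The deposited table holds a processed intensity for each of 22690 probe sets on each of the 6 arrays. RMA, which corrects background, equalises array distributions and summarises the probes of a probe set, is the tool that the submitters' processing notes name, and its software, version and options are not given in the sources used here. RMA reports log2 values by default, but the deposited intensities are on a linear scale, from about 5 to 21219, so they were taken as back-transformed. Values of YY1bKO replicate 3 carry fewer decimals than those of the other arrays. No missing values and no duplicated probe sets or arrays were found. The table holds no detection calls, so a dim probe set was defined as one with a mean over the 6 arrays at or below the median of all probe sets, a log2 intensity of 6.48. Array medians lay between 6.46 and 6.48 on the log2 scale.

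RMA can affect the measurements in 2 ways that bear on every value. It forces the arrays to 1 distribution, which hides a shift of most transcripts in 1 direction, and its background model pulls in the fold changes of dim probe sets, so that those understate a change. The median log2 fold change over all genes was 0.04.

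The design had been planned for log2 values, and the intensities were therefore transformed to log2 without a pseudocount before any test, since none was at or below 0. Probe sets were named through the platform annotation paired with the table and through a gene table of GRCm38.p6, which was used for names and for which genes neighbour each other. Of 22626 probe sets left after removing 64 Affymetrix control probe sets, 20380 had 1 gene symbol, 691 had several and 1555, or 6.87%, had none here. Entrez identifiers matched for 20351 of them, and 0 symbols changed. Each of the 12393 genes was represented by its named probe set with the highest mean over all 6 arrays. Probe sets with several genes or none were left out of the gene tests.

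The main comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior and no trend), with group as the sole term and all 6 arrays. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. Every adjusted p for a gene in the text is from limma's moderated test. The prior held 2.71 and the residual 4 degrees of freedom. SE is the moderated standard error of a log2 fold change. Quantities that are a single value per array were compared by an exact permutation test, which cannot go below 0.1 with 3 against 3. Nothing in the labels says that replicates are separate animals, so p-values measure the spread between these samples, which may be technical. No scan date or processing batch is given in the sources used here.

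Gene lists were fixed before the data were examined: 41 lists covering the thermogenic program, the secreted proteins named by the study, brown adipose secreted factors, mitochondrial complexes and metabolism, lipid, cholesterol and sugar metabolism, stress responses, proliferation, interferon and inflammation, matrix, peroxisome, ribosomal proteins, clock and immediate early genes, calcium cycling, markers of 10 other cell types, sex-linked genes and genes neighbouring Ucp1. The 38 lists with at least 4 measured genes, quality checks aside, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Of these, 3 were called higher and 6 lower. With a correlation estimated from the 6 arrays for each list, 0 lists were called, the smallest adjusted p being 0.92, and 1 list had an unadjusted p under 0.05. The directional test fry called 4 lists higher and 3 lower, and its mixed test, which asks whether genes of a list change in either direction, called 33. Neither compares a list with other genes. For each list the number of called genes is given over all genes and adjusted over the list alone.

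Genes named in the text were chosen by a rule set before the data were examined: Yy1, the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, up to 4 members of each described list by smallest p, Ucp1, Ppargc1a, Dio2, Cidea, Fgf21 and the measured secreted proteins of the study whatever their values, and sex-linked genes as a check. Some genes fixed for naming and some list members are not analysed here. Lists of fast-fibre and slow-fibre muscle genes, and a fit with the mean of the muscle list as a covariate, were added after the data had been seen.

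Alternatives tried were leaving out dim genes, the mean over all probe sets of a gene, quantile normalization, median centring, eBayes with trend and robust options, array weights, the replicate number as a block, an added fold of at least 1.5, an adjusted p under 0.1, every probe set in place of genes, and each array left out in turn. The gene test was tested on simulated data with the means and variances of the 12393 genes, 200 of them changed. It recovered 37.1% of 70 genes changed by 0.5 on the log2 scale, 90.6% of 64 changed by 1 and 100% of 66 changed by 2, and 4 unchanged genes were called, 2.60% of all calls. In simulated data with the interferon list shifted by 0.5, camera called that list and 0 of 36 unshifted lists. The simulated data were set from the means and variances of the genes. In the real data, the estimated correlation was 0.34 in the interferon list and 0.68 in fatty acid oxidation, above the preset 0.01. The 0 unshifted lists called therefore do not give the error rate of camera at such correlations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.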

Results

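Transcripts of mouse brown adipose tissue, the fat depot specialised in making heat, were profiled on Affymetrix expression arrays. The mice were 3.5 months old, of mixed C57BL6 and 129 descent, and had eaten high fat food during 3 months. The control group held 3 arrays from mice with both Yy1 alleles floxed, and the YY1bKO group held 3 arrays from floxed mice that also carried Ucp1Cre, a Cre recombinase expressed from the promoter of the brown adipocyte gene Ucp1. Yy1 encodes the zinc finger transcription factor Yin Yang 1. The comparison asks which transcripts of the tissue, those for secreted proteins in particular, differ when brown adipocytes lose this factor under such feeding. Each array gave intensities for 22690 probe sets, and 12393 genes could be tested. Pearson's r across genes was 0.978 to 0.996 between control arrays, 0.996 between YY1bKO arrays, and 0.976 to 0.985 between arrays of different groups. The first principal component held 48.6% of the variance and parted the groups, and the second held 36.0% and parted control replicate 2 from the other 5 arrays. With 3 arrays per group, their number limits the precision of every value.

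Yy1 itself was lower in all 3 YY1bKO arrays. Its brightest probe set had a log2 intensity of 9.82 ± 0.18 (SD, n = 3) in control and 8.39 ± 0.02 (SD, n = 3) in YY1bKO tissue. The log2 fold change was -1.43 ± 0.10 (SE), or 2.69-fold lower (limma adjusted p = 0.000854). Another bright probe set of Yy1 gave -1.71, a dim one gave -0.81 (adjusted p = 0.0103), and the dimmest, at 4.55 in control and 4.49 in YY1bKO, gave -0.06 (adjusted p = 0.766). Where these probes lie relative to the deleted part of the gene is not given in the sources used here, so the values show a lower transcript level and not the deletion itself.

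**Figure D1:**
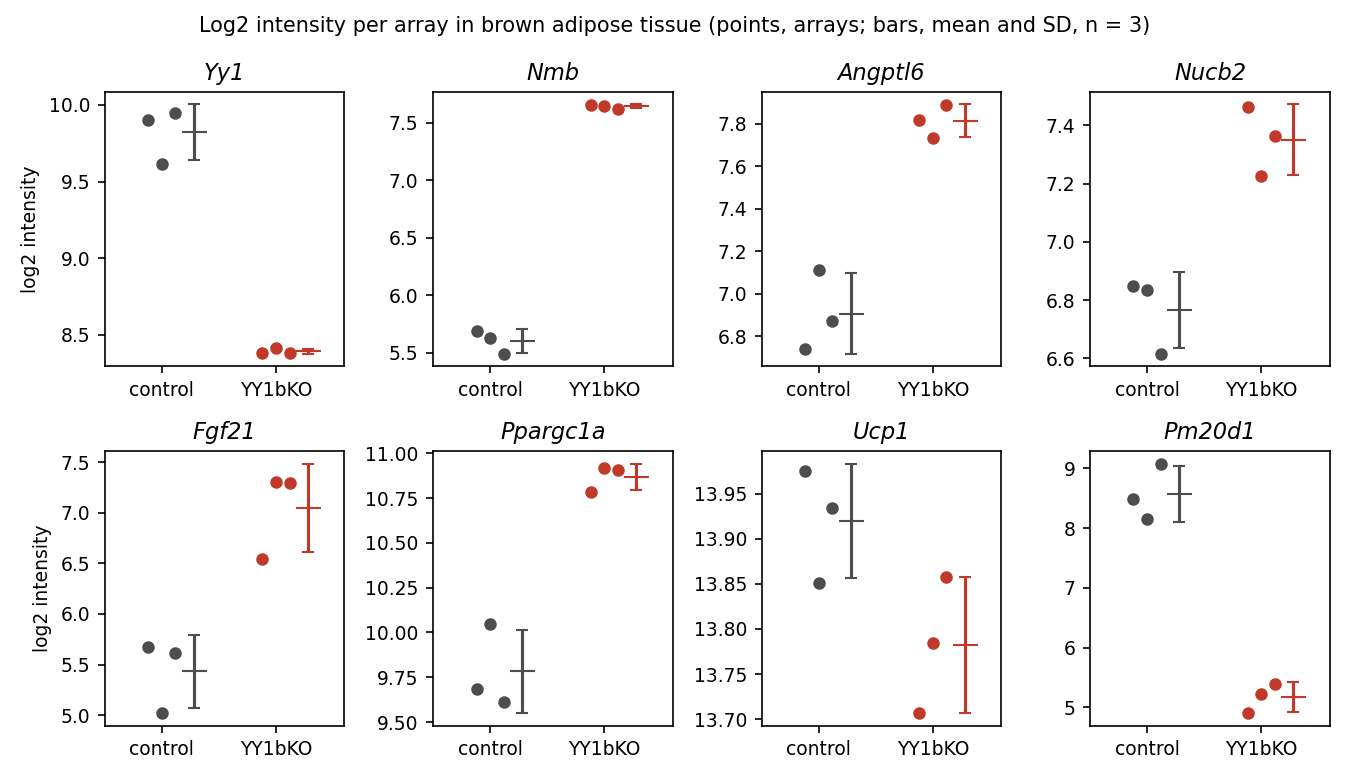
Log2 intensity (vertical axes, ranges differ) of 8 genes in the 3 control and 3 YY1bKO arrays, with each array as a point and the group mean and SD beside the points. Yy1 and Pm20d1 lie lower in the 3 YY1bKO arrays, Nmb, Angptl6, Nucb2, Fgf21 and Ppargc1a lie higher, and the Ucp1 values of the groups overlap.

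YY1bKO tissue had 1267 genes higher and 1003 genes lower than control tissue at an adjusted p under 0.05, which is 18.3% of the genes tested. Of these, 132 were at least 2-fold higher and 173 at least 2-fold lower. In all 2270 called genes the 3 YY1bKO values lay on 1 side of the 3 control values, and over all genes this held for 4769, or 38.5%, where chance gives 10%. The counts moved when an array was left out: 678 higher and 541 lower without control replicate 1, 1661 and 1439 without control replicate 2, 946 and 792 without control replicate 3, 555 and 513 without YY1bKO replicate 1, 547 and 466 without YY1bKO replicate 2, and 570 and 492 without YY1bKO replicate 3. Poly-A control transcripts added to the RNA during labelling also differed, with a mean log2 intensity of 7.32 ± 0.15 (SD, n = 3) in control and 6.99 ± 0.10 (SD, n = 3) in YY1bKO arrays, and the groups did not overlap (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow).

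The largest rises among the brightest probe sets of each gene were those of Psrc1 and Ifnz. Their control log2 intensities, 4.82 ± 0.52 and 5.53 ± 0.37 (SD, n = 3), lay below the median of all probe sets. Psrc1, a protein of the mitotic spindle, was 11.5-fold higher (log2 fold change 3.52 ± 0.25, SE, adjusted p = 0.000807) in its brightest probe set. Its log2 fold change was 1.49 in the mean over its probe sets. Ifnz, a type I interferon, was 9.68-fold higher (3.27 ± 0.18, adjusted p = 0.000479). Cyp2e1, a cytochrome P450, rose 5.29-fold and Usp18, which removes the ubiquitin-like protein Isg15 from its targets, rose 4.48-fold. The desaturase gene Scd3 rose 4.67-fold and Sln, which encodes the calcium pump regulator sarcolipin, rose 5.57-fold, both from dim intensities. The Sln log2 fold change was 1.28 in the mean over its probe sets. Nmb, the neuropeptide neuromedin B, rose 4.11-fold. The remaining genes among the 12 largest rises were Cahm, Gm7008, Tmem260, C920021L13Rik and Rab26os, at 5.22-fold to 7.64-fold, and 4 of these, all except C920021L13Rik, had a mean below the median of all probe sets.

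The largest fall was that of Pm20d1, a secreted enzyme that couples fatty acids to amino acids, which was 10.6-fold lower (log2 fold change -3.40 ± 0.25, SE, adjusted p = 0.000836). S100b, a calcium-binding protein made by glia and brown adipocytes, was 5.49-fold lower from a bright control level (11.57 ± 0.10 in control, 9.12 ± 0.31 in YY1bKO, SD, n = 3). Ptgds, a prostaglandin D synthase, was 5.02-fold lower, and Cpn2, the non-catalytic subunit of the plasma enzyme carboxypeptidase N, 5.49-fold lower. Suclg2, a subunit of the mitochondrial enzyme succinyl-CoA synthetase, was 4.74-fold lower (adjusted p = 0.000306), the mitochondrial protein gene Nipsnap1 5.44-fold lower, and Acsm3, a medium-chain acyl-CoA synthetase, 5.02-fold lower. The Acsm3 call (adjusted p = 0.0172) was lost without control replicate 1 (adjusted p = 0.0601), YY1bKO replicate 1 (0.0689) or YY1bKO replicate 3 (0.0694). Zdhhc2, a palmitoyltransferase, was 5.68-fold lower, and Mal2, Myo5c, Plppr4 and Car12 were 4.54-fold to 7.94-fold lower at dim intensities.

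Ucp1, the uncoupling protein that lets brown fat mitochondria make heat, showed no called difference (13.92 ± 0.06 in control, 13.78 ± 0.08 in YY1bKO, SD, n = 3), with a log2 fold change of -0.14 ± 0.08 (SE, adjusted p = 0.292). Both means lie near the top of the intensity range of the arrays. Cidea, a lipid droplet protein of brown adipocytes, gave -0.12 ± 0.09 (adjusted p = 0.447), with means of 13.74 and 13.63 likewise near the top. Dio2, the deiodinase that activates thyroid hormone, gave -0.87 ± 0.38 (adjusted p = 0.176), or -0.55 in the mean over its probe sets. Ppargc1a, a coactivator of mitochondrial gene transcription, was 2.12-fold higher (1.09 ± 0.13, adjusted p = 0.00356). Its log2 fold change was 0.61 in the mean over its probe sets (adjusted p = 0.0331). Of the 25 measured genes of the thermogenic program list, 3 were higher and 5 lower, and 3 and 6 when adjusted over the list alone. Zic1 rose by 0.90 and the fatty acid carrier Fabp3 fell by 0.75 on the log2 scale. The list as a set did not pass the test (camera adjusted p = 0.132). The higher and lower counts were 2 and 2 without control replicate 1 or YY1bKO replicate 3, 2 and 3 without YY1bKO replicate 1 or 2, and 4 and 3 without control replicate 3.

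Genes of respiratory complex I, the proton-pumping NADH dehydrogenase of mitochondria, fell as a group. Among 32 measured complex I genes, 9 were lower and 2 higher, and 12 and 3 when adjusted over the list alone, with a list median of -0.14 (camera adjusted p = 0.00215, and adjusted p = 0.92 with an estimated correlation). Ndufa5 fell by 0.97 (adjusted p = 0.00189), Ndufb8 by 0.69, Ndufa13 by 0.64 and Ndufs7 by 0.58 on the log2 scale. The count of higher genes was 0 without control replicate 1 or any of the 3 YY1bKO arrays, and 1 without control replicate 3. In the list of complexes II and III, 3 of 14 genes were lower, also when adjusted over the list alone, Uqcrc1 with -0.59 among them (camera adjusted p = 0.113), and the Uqcrc1 call was lost without YY1bKO replicate 1 or 2. No gene of 18 in complex IV was called by limma, over all genes or adjusted over the list alone, and 1 was higher and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.96). When dim probe sets were left out, Cox7a2l was called lower (-0.33, adjusted p = 0.0357) and Cox7a2 higher (0.24, adjusted p = 0.0309). Of 16 ATP synthase genes Atp5j2 was lower, with -0.27, none was called when adjusted over the list alone, and the Atp5j2 call was lost after quantile normalization and when any array except control replicate 2 was left out (camera adjusted p = 0.514). When dim probe sets were left out, Atp5o (adjusted p = 0.0301) and Atp5g2 (0.0474) were called lower and Atp5g3 higher (0.0398). In the mean over the probe sets of each gene Atp5o was also called (-0.39, adjusted p = 0.0119), and Atp5g2 was not (-0.11, adjusted p = 0.379).

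The tricarboxylic acid cycle list held 6 lower and 0 higher genes among 20, and 7 and 0 when adjusted over the list alone. Its median was -0.23 (camera adjusted p = 8.79e-05, and adjusted p = 0.92 with an estimated correlation), and fry did not call it (adjusted p = 0.0546). Subunits of succinyl-CoA synthetase lay among them, with Suclg2 at -2.25, Suclg1 at -0.50 and Sucla2 at -0.38, and the Suclg1 and Sucla2 calls were lost without control replicate 1, YY1bKO replicate 1 or YY1bKO replicate 2, that of Sucla2 also without control replicate 3 or YY1bKO replicate 3. The count of lower genes was 1 without control replicate 1, 3 without control replicate 3, 11 without control replicate 2, and 1, 1 and 2 without YY1bKO replicates 1, 2 and 3. Fatty acid oxidation genes moved both ways, with 4 lower and 2 higher of 22, also when adjusted over the list alone, and a list median of -0.08 (camera adjusted p = 0.0333, and adjusted p = 0.92 with an estimated correlation). Echs1, an enoyl-CoA hydratase, fell by 0.89, while Acsl5, which activates long-chain fatty acids, rose by 1.19 and the thioesterase Acot2 by 1.02. Those 2 rises lost their calls without YY1bKO replicate 1, that of Acot2 also without control replicate 1 or YY1bKO replicate 2, and that of Acsl5 without YY1bKO replicate 3. The number of lower genes was 2 without any array except control replicate 2, and that of higher genes 0 without YY1bKO replicate 1 and 1 without control replicate 1, YY1bKO replicate 2 or YY1bKO replicate 3. The call of the list was lost without control replicate 1 (adjusted p = 0.125), control replicate 3 (0.205) or YY1bKO replicate 2 (0.0774). It was also lost when dim probe sets were left out (adjusted p = 0.156), after quantile normalization (0.130) and with fry (0.362). The same held with the muscle score, the mean of the skeletal muscle genes, as a covariate (camera adjusted p = 0.344). The median of the list was -0.05 without control replicate 1, -0.20 without control replicate 2, -0.04 without control replicate 3, -0.15 in the mean over probe sets, -0.14 with array weights and -0.02 with the muscle score.

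Mitochondrial ribosome genes were split, 12 higher and 14 lower of 57, and 16 and 16 when adjusted over the list alone (camera adjusted p = 0.754). Mrpl19 fell by 1.10, Mrpl37 by 0.83, Mrpl49 by 0.80 and Mrps24 by 0.73 on the log2 scale. The counts were 5 and 7 without control replicate 1, 8 and 7 without control replicate 3, 5 and 7 without YY1bKO replicate 1 or 3, and 5 and 9 without YY1bKO replicate 2. Of 16 genes for the upkeep and transcription of the mitochondrial genome, 3 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.865). Ssbp1, a DNA-binding protein of mitochondria, rose by 0.59, and Tfam, which packages and transcribes mitochondrial DNA, rose by 0.35, a call lost when any array except control replicate 2 was left out.

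The study named secreted proteins linked to energy expenditure, and the 3 of them measured here were higher. Nmb had a log2 intensity of 5.60 ± 0.10 in control and 7.64 ± 0.02 in YY1bKO (SD, n = 3), a log2 fold change of 2.04 ± 0.08 (SE, adjusted p = 0.000306). Angptl6, an angiopoietin-like protein, was 1.87-fold higher (0.91 ± 0.11, adjusted p = 0.00437). Nucb2, the precursor of nesfatin, was higher by 0.59 ± 0.10 on the log2 scale (SE, adjusted p = 0.0123), and its call was lost without YY1bKO replicate 1 (0.53, adjusted p = 0.0518) or YY1bKO replicate 3 (0.58, adjusted p = 0.0525). All 3 were also called when adjusted over the list alone, and since the study chose this list on these samples, its direction is not independent evidence. Fgf21, a hormone of energy balance, was 3.07-fold higher (1.62 ± 0.26, adjusted p = 0.00901) at dim intensities of 5.43 ± 0.36 and 7.05 ± 0.44 (SD, n = 3).

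A separate list, fixed as brown adipose secreted factors, had 10 lower and 3 higher genes of 35 measured, the same numbers when adjusted over the list alone. Its median was -0.19 (camera adjusted p = 0.0027, and adjusted p = 0.92 with an estimated correlation). Without YY1bKO replicate 3 the count of lower genes was 6, and the median was -0.38 when dim probe sets were left out. Pm20d1, Ptgds and S100b fell, as given above. The clearest rise was that of Ephx1 (1.91 ± 0.09, SE, adjusted p = 0.000328), a microsomal epoxide hydrolase that acts inside cells. Not every member of the list is therefore a released protein. Fgf21, given above, was also among the higher genes of the list. Lep, the adipocyte hormone leptin, was 4.01-fold lower (adjusted p = 0.00881). It is also a member of the white adipocyte list, of whose 17 genes 1 was lower and 1 higher, the serine synthesis gene Psat1 with 0.96, also when adjusted over the list alone (camera adjusted p = 0.865).

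Interferon-stimulated genes were higher as a group. Of 25 measured, 18 were higher and 0 lower, and 20 and 0 when adjusted over the list alone, with a list median of 0.68 (camera adjusted p = 1.25e-10, and adjusted p = 0.92 with an estimated correlation). Usp18 rose by 2.16 ± 0.15 (SE), the chemokine gene Cxcl10 by 1.70 ± 0.17, the guanylate-binding protein gene Gbp3 by 1.04 ± 0.08 and the peptide transporter gene Tap1 by 0.68 ± 0.08. Of 4 Tap1 probe sets 3 went the same way, and its call was lost in the mean over its probe sets. Leaving out any single array left 15 to 18 of the 25 called higher. Inflammatory cytokines and chemokines did not pass the test as a set, with 2 higher and 2 lower of 26, also when adjusted over the list alone (camera adjusted p = 0.742). The higher ones were Cxcl10 and Ccl5 (1.53 ± 0.12, adjusted p = 0.00106), and the lower ones were Icam1 (-0.75) and Lcn2 (-1.32), whose calls were lost without control replicate 1, YY1bKO replicate 1 or YY1bKO replicate 2, that of Lcn2 also without YY1bKO replicate 3.

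**Figure D2:**
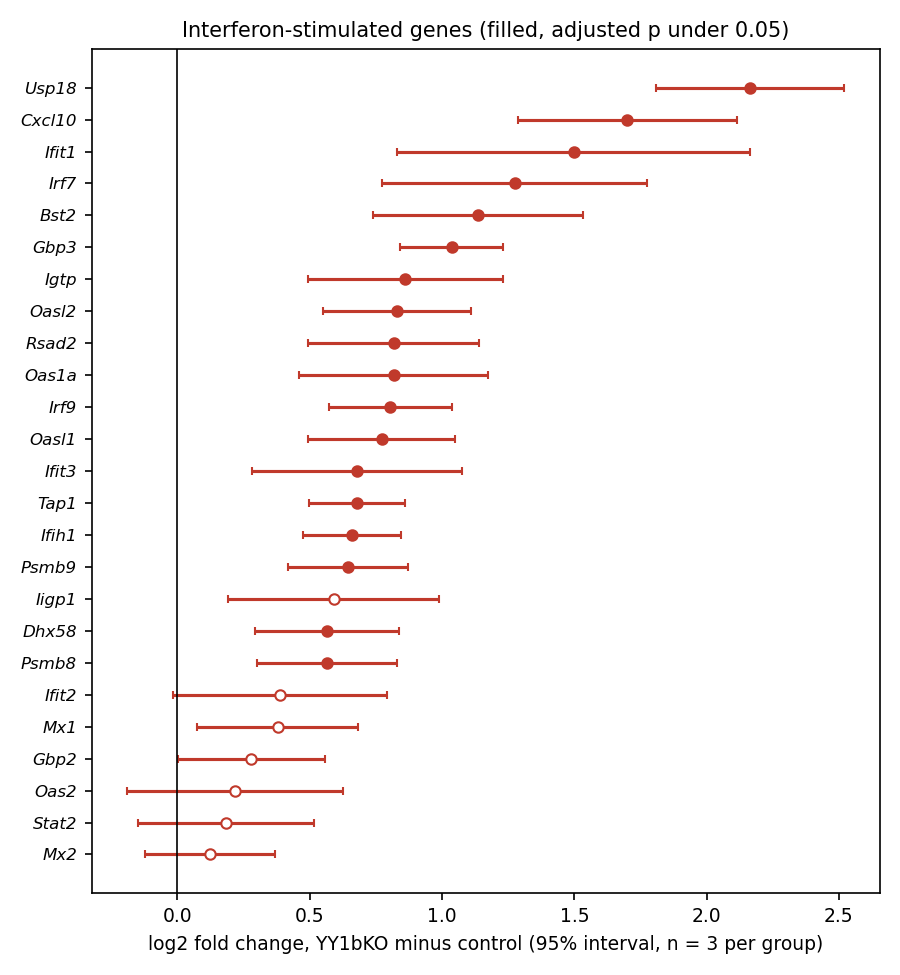
Log2 fold change of YY1bKO minus control (horizontal axis) for the 25 measured interferon-stimulated genes, as points with 95% intervals from 3 arrays per group, filled where the adjusted p was under 0.05. The fold changes run from 0.12 to 2.16, and 18 of the 25 points are filled.

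Of 19 measured genes of the p53 response, 7 were higher and 1 lower, and 8 and 2 when adjusted over the list alone, and the set did not pass (camera adjusted p = 0.0872). It passed as higher without control replicate 1 (adjusted p = 0.0368) or control replicate 2 (0.0172), and with fry (0.0338). Zmat3, an RNA-binding target of p53, rose by 1.87 ± 0.18 (SE), Cdkn1a, a cyclin-dependent kinase inhibitor, by 1.71 ± 0.22, and Mdm2, the ubiquitin ligase of p53, by 0.77 ± 0.09, with adjusted p of 0.00189, 0.00473 and 0.00322. Plk2 fell by 0.74. The count of higher genes was 4 without control replicate 1 and 3 without control replicate 3, YY1bKO replicate 1 or YY1bKO replicate 2. In the proliferation list 1 gene of 28 was called, the mitotic kinesin gene Kif11 with 0.87 at a dim intensity, and only 1 of its 3 probe sets went that way (1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.247). This list passed as lower with array weights (adjusted p = 0.0372), where Ccna2 and Ube2c were called lower. The integrated stress response list held 11 higher and 2 lower genes of 41, and 13 and 3 when adjusted over the list alone (camera adjusted p = 0.139). It passed as higher without YY1bKO replicate 1 (adjusted p = 0.0163). The amino acid transporter subunit gene Slc3a2 rose by 1.88 ± 0.10 and the folate enzyme gene Mthfd2 by 0.67 ± 0.09 (1.07 in the mean over its probe sets), while Vldlr fell by 0.52. Counts of higher genes here were 7 without control replicate 1, 6 without control replicate 3, and 4 and 5 without YY1bKO replicates 2 and 3, and counts of lower genes lay between 1 and 5, with 5 without control replicate 2.

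Genes of the unfolded protein response of the endoplasmic reticulum were higher in 5 of 23 and lower in 0, also when adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.0301, and adjusted p = 0.92 with an estimated correlation). Sec61b, part of the translocation channel, rose by 0.67 and the oxidase gene Ero1a by 0.72, a call lost without YY1bKO replicate 2 or 3. The set call was lost without control replicate 2 (adjusted p = 0.111) or YY1bKO replicate 3 (0.113), in the mean over the probe sets of each gene (0.137) and with array weights (0.0987). The set was not called by fry (adjusted p = 0.186). Between 1 and 3 genes were called when any array was left out, with 3 for each control and 2, 2 and 1 for YY1bKO replicates 1, 2 and 3. The mitochondrial unfolded protein response list had 2 higher and 2 lower genes of 14, also when adjusted over the list alone (camera adjusted p = 0.925), the protease gene Lonp1 with 0.68 and Spg7 with -0.66 (not called without YY1bKO replicate 1 or 2) among them. The antioxidant targets of NRF2 had 3 higher and 3 lower of 20, and 4 and 3 when adjusted over the list alone (camera adjusted p = 0.865), with Ephx1 highest, and the glutathione transferase genes Gstm2 and Gstm1 lower with -1.07 and -0.60.

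Genes of cytosolic ribosomal proteins were higher in 17 of 37 and lower in 0, and 25 and 0 when adjusted over the list alone, with a median of 0.28 (camera adjusted p = 6.05e-06, and adjusted p = 0.92 with an estimated correlation). Rpl27 rose by 0.54, Rps18 and Rps10 by 0.43 each and Rpl19 by 0.42, and the calls of Rps18, Rps10 and Rpl19 were lost without YY1bKO replicate 1 or 2, those of Rps18 and Rps10 also without YY1bKO replicate 3. The control probe sets for 18S ribosomal RNA were also higher. Their mean log2 intensity was 12.83 ± 0.08 in control and 13.35 ± 0.07 in YY1bKO arrays (SD, n = 3), which is 1.43-fold higher with no overlap (two-sided exact permutation p = 0.1, the smallest possible). Since the poly-A control transcripts differed too, a labelling difference cannot be told apart from more ribosomal RNA. The count of higher ribosomal protein genes was 7 without control replicate 1, 6 without control replicate 3, and 1, 1 and 2 without YY1bKO replicates 1, 2 and 3.

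Lists of fatty acid and triglyceride synthesis, lipolysis and lipid droplets, cholesterol synthesis, and glycolysis did not pass the test as sets in the main fit. Only some of their genes were called. Of 20 genes for fatty acid and triglyceride synthesis, 3 were lower and 0 higher, also when adjusted over the list alone (camera adjusted p = 0.404). These were Pck1 (-1.09), Acss2 (-0.95) and Dgat2 (-0.83), which act in glyceroneogenesis, acetate activation and triglyceride assembly, with -0.56 for Pck1 in the mean over its probe sets. Of 15 lipolysis and lipid droplet genes, 2 were lower, the glycerol channel gene Aqp7 (-0.78, or -0.43 in the mean over its probe sets) and the lipase inhibitor gene G0s2 (-0.77), and 3 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.148). The lipolysis set passed as lower without control replicate 2 (adjusted p = 0.0107) and with array weights (0.0455). The Acss2 and G0s2 calls were lost without control replicate 1 or any YY1bKO array, that of G0s2 also without control replicate 3. The cholesterol synthesis list held 4 higher and 1 lower of 19, and 5 and 1 when adjusted over the list alone (camera adjusted p = 0.161). That set passed as higher without control replicate 3 (adjusted p = 0.0460) and with the muscle score (0.0393). Sqle rose by 0.76, Idi1 by 0.65 and Msmo1 by 0.58, and Fdft1 fell by 0.87, with 2 of its 4 probe sets going the other way and its call lost in their mean. These 4 calls were lost without YY1bKO replicate 2, those of Sqle, Idi1 and Msmo1 also without YY1bKO replicate 1, and those of Idi1 and Msmo1 without control replicate 1 or YY1bKO replicate 3. Of 17 glycolysis genes 2 were higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.245). Slc2a4, the insulin-regulated glucose transporter, rose by 0.99 and Slc2a1, the basal one, fell by 0.80, a call lost without YY1bKO replicate 1 or 2.

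**Figure D3:**
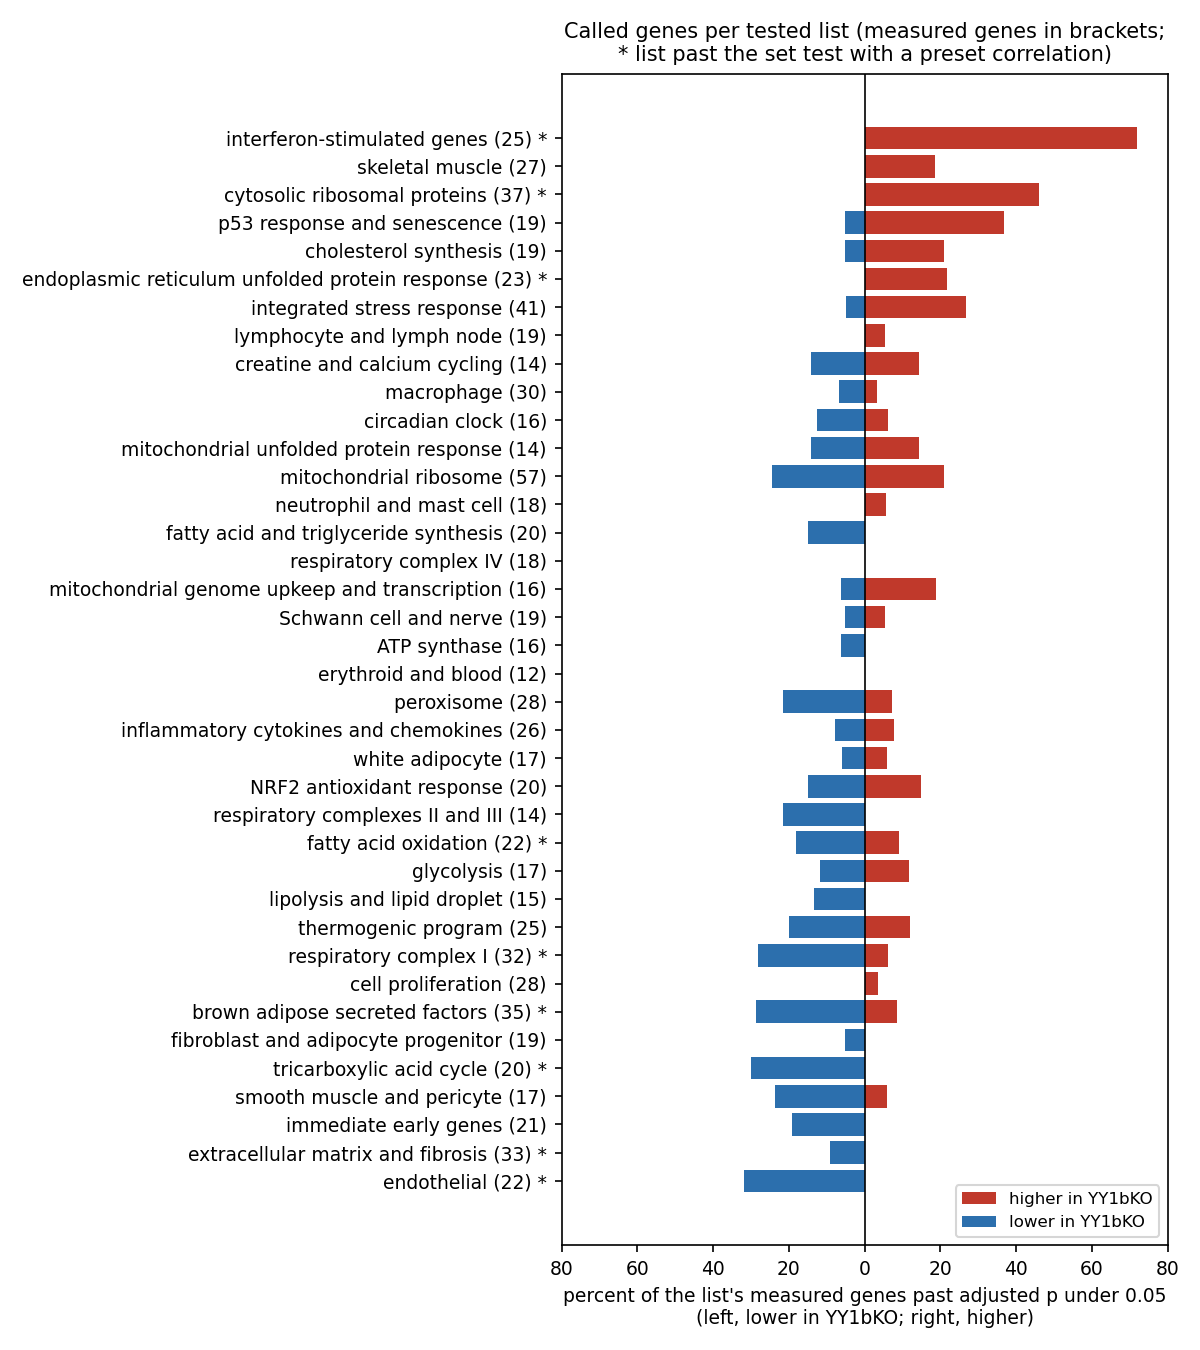
Share of the measured genes (in brackets) of each of the 38 lists tested by camera that were called higher (right, red) or lower (left, blue) in YY1bKO, in percent, with lists ordered by median log2 fold change and an asterisk where camera with a preset correlation passed. Interferon-stimulated genes, 18 of 25 higher, reach farthest right, and endothelial genes, 7 of 22 lower, farthest left.

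Endothelial markers, genes of the cells that line blood vessels, fell as a group. Of 22 endothelial genes, 7 were lower and 0 higher, and 11 and 0 when adjusted over the list alone, with a median of -0.47 (camera adjusted p = 6.05e-06, and adjusted p = 0.92 with an estimated correlation). The receptor genes Kdr and Tek fell by 0.53 and 0.65, the junction gene Cdh5 by 0.53 and the transcription factor gene Sox17 by 0.74 on the log2 scale, and none of these 4 calls held in every fit with an array left out. Those of Cdh5 and Tek were lost without YY1bKO replicate 2 or 3, those of Tek and Kdr without control replicate 1, that of Kdr without YY1bKO replicate 1, and that of Sox17 without control replicate 3 or any YY1bKO array. The count of lower genes was 3 without control replicate 1, 12 without control replicate 2, and 3, 1 and 3 without YY1bKO replicates 1, 2 and 3. In the smooth muscle and pericyte list 4 of 17 were lower, the pericyte genes Cspg4 (-0.95), Rgs5 (-0.53), Notch3 (-0.53) and Kcnj8 (-0.56), and 1 was higher, with 4 and 2 when adjusted over the list alone (camera adjusted p = 0.202). This set passed as lower without control replicate 3 (adjusted p = 0.0439) and with the muscle score (0.0185). The Notch3 and Kcnj8 calls were lost without control replicate 1 or YY1bKO replicate 2, that of Notch3 also without YY1bKO replicate 1 and in the mean over its probe sets, and that of Kcnj8 without YY1bKO replicate 3. Extracellular matrix genes had a median of -0.34 (camera adjusted p = 0.00215, and adjusted p = 0.92 with an estimated correlation), and 3 of 33 were lower, also when adjusted over the list alone. The set call was lost when dim probe sets were left out (adjusted p = 0.0578) and with fry (0.432), and the median was -0.23 without control replicate 1. These were Lox, which crosslinks collagen (-1.73 ± 0.28, SE, adjusted p = 0.00951), Tnc (-1.15) and Bgn (-0.78), with the Tnc and Bgn calls lost without control replicate 1, YY1bKO replicate 1 or YY1bKO replicate 2, that of Bgn also without YY1bKO replicate 3. That count was 1 without control replicate 1, YY1bKO replicate 1 or YY1bKO replicate 2, 7 without control replicate 2 and 12 without control replicate 3. Of 19 fibroblast and progenitor genes 1 was lower, Pdgfrb with -0.77, and 0 when adjusted over the list alone (camera adjusted p = 0.113), a call lost when any array except control replicate 3 was left out. The fibroblast set passed as lower without control replicate 3 (adjusted p = 5.95e-05) and with the muscle score (0.00125).

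Markers of skeletal muscle differed between arrays of the same group. In control replicate 2 the median of 27 muscle genes lay 5.53-fold above the other 2 control arrays, and in the YY1bKO arrays it lay 2.48-fold above them. In the main comparison 5 muscle genes were higher and 0 lower, also when adjusted over the list alone (median 0.45, camera adjusted p = 0.0872). Myh7, the myosin heavy chain of slow fibres, rose by 1.72 ± 0.23 (SE), the slow troponin genes Tnnt1 and Tnnc1 by 1.59 ± 0.20 and 1.58 ± 0.20, and Sln by 2.48 ± 0.37. Without control replicate 2 the count was 26 and the set passed (adjusted p = 4.32e-14), as it also did with array weights (4.76e-05) and without YY1bKO replicate 3 (0.0271). Without control replicate 3 the median of the muscle list was -0.04 (camera adjusted p = 0.619). The creatine and calcium cycling list shares Sln with the muscle list and held 2 higher and 2 lower of 14, also when adjusted over the list alone (camera adjusted p = 0.754), with the creatine kinase gene Ckb at -0.76. With the muscle score the creatine set had a median of -0.41 and passed as lower (adjusted p = 0.0155).

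**Figure D4:**
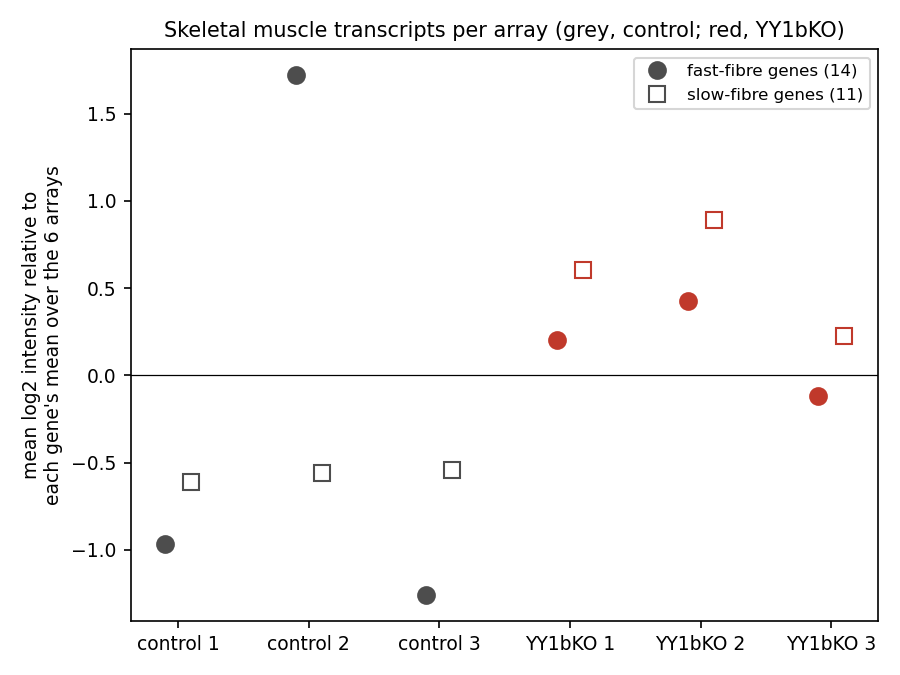
Mean log2 intensity relative to each gene's mean over the 6 arrays (vertical axis) of 14 fast-fibre (filled circles) and 11 slow-fibre (open squares) muscle genes in each array, grey for control and red for YY1bKO. Control replicate 2 has the highest fast-fibre mean, 1.72, and the 3 YY1bKO arrays have slow-fibre means from 0.22 to 0.89, above the 3 controls.

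Few markers of immune cells, nerve and blood were called. Of 30 macrophage genes 1 was higher, Ms4a7 (0.79), and 2 were lower, Cd163 (-0.79) and Msr1 (-0.33), and 0 were called when adjusted over the list alone (camera adjusted p = 0.925). The macrophage set had a median of -0.11 and passed as lower without control replicate 3 (adjusted p = 0.0314). Of 19 lymphocyte genes 1 was higher, Cd3d with 0.50, and of 18 neutrophil and mast cell genes 1 was higher, the histidine decarboxylase gene Hdc with 0.42, with 0 called in either list when adjusted over the list alone (camera adjusted p = 0.161 and 0.514). The lymphocyte list was called higher by fry (adjusted p = 0.0492), and 17 of its 19 genes were dim. The calls of Ms4a7, Cd163, Msr1, Cd3d and Hdc were lost without YY1bKO replicate 2 or 3, that of Msr1 also in the mean over its probe sets. The Schwann cell and nerve list had 1 gene lower, S100b, which brown adipocytes also make, and 1 higher, the myelin gene Mal with 0.40, of 19 (the Mal call was lost in the mean over its probe sets and when any array except control replicate 2 was left out), also when adjusted over the list alone (camera adjusted p = 0.925). No gene of 12 in the erythroid list was called by limma, over all genes or adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05 (camera adjusted p = 0.514). Hbb-b2 and Alas2 were called lower without control replicate 2 (adjusted p = 0.0105 and 0.0154). Among 5 sex-linked genes limma called 0 over all genes, and 1 higher and 3 lower when adjusted over the list alone, the same as at an unadjusted p under 0.05. The Y-linked gene Uty was called lower without control replicate 2 (adjusted p = 0.0048), and with array weights Uty was called lower and Xist higher (adjusted p = 0.0335 for Xist). Xist was dim (4.29 ± 0.12 in control, 4.66 ± 0.16 in YY1bKO, SD, n = 3), and the Y-linked gene Eif2s3y was expressed in both groups (9.40 ± 0.05 and 9.12 ± 0.19, SD, n = 3). The median, the mean and the camera direction did not share a sign in the lists of ATP synthase, fatty acid and triglyceride synthesis, mitochondrial ribosome, mitochondrial unfolded protein response, creatine and calcium cycling, white adipocyte, macrophage, and Schwann cell and nerve genes.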

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

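Tests of chance splits, spike transcripts, immune cells behind the interferon genes and muscle fibres were chosen after the results were seen. Those of strain segments and probe variants were chosen before. The test of muscle behind the interferon genes is recorded as set before, but it rests on the muscle transcripts of control replicate 2. It was therefore not chosen independently of the data. The control probe sets for 18S ribosomal RNA, which lie outside the gene comparison, were higher in the 3 YY1bKO arrays than in the 3 controls by 0.52 on the log2 scale. Of 2246 probe sets with no gene or several genes here, which also lie outside the gene comparison, 211 were called higher in YY1bKO tissue and 119 lower, 29 and 26 of them by at least 2-fold.

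The largest pattern is the number of called genes. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many as 1267 genes higher, and only 1 gave as many as 1003 lower, the highest count of any other split being 0 in both directions, but 10 splits are too few to give a share under 0.05. Every other split also mixes the 2 groups, so a difference between them widens its spread, and counts near 0 were likely in advance. On a mixed background, chromosome segments of 129 or C57BL6 descent that differ between the groups could place many of the 305 genes changed by at least 2-fold side by side. Of these genes 76 had another within 5 tested genes, against 67.2 at random, an excess share of 0.0289 (95% permutation interval -0.0328 to 0.0918). That argues against segments dense in such genes as the main source. It cannot exclude single segments, or segments with few such genes. On chromosome 3, for instance, Psrc1 and Plppr4 lay in a stretch with several such genes. Strain variants under the probes would leave other probe sets of a gene unmoved, but a share of 0.988 of 84 other bright probe sets of 58 such genes moved the same way (exact 95% interval 0.935 to 1.000). The rest of the 305 genes had no other bright probe set, so variants under their probes were not checked. Poly-A spike transcripts differed by -0.335 on the log2 scale between the groups, 15 of 24 spike probe sets without overlap, while the hybridisation spikes, added after labelling, overlapped (mean 10.74 in control and 10.77 in YY1bKO, two-sided exact permutation p = 0.8), so labelling of the groups in separate batches cannot be told apart from the genotype and stays open beside the loss of Yy1, which was not tested as a cause.

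The rise of interferon-stimulated genes could come from more macrophages in the tissue. The 22 macrophage genes that are not dim had, however, a median change of 0.168. Its 95% bootstrap interval (-0.0357 to 0.238) lay below the lower limit of 0.567 for the interferon list. Bootstrap intervals here are over genes, which move together, and leave out the spread between arrays. Per array, means of the full macrophage list overlapped between the groups (-0.44 to 0.22 in control, -0.05 to 0.16 in YY1bKO). More lymphocytes stay open, since only 2 of the 19 lymphocyte genes are not dim, with a median of 0.149, and fry called the list higher (adjusted p = 0.0492). More muscle of the fast-fibre kind in the YY1bKO samples is argued against by control replicate 2, which had the most muscle transcripts. Its interferon genes deviated from the other controls by a median of -0.0503 (-0.100 to 0.0695). Over all 6 arrays, the fit with the muscle score as a covariate had 19 of the 25 genes higher with a median of 0.68. Neither check separates slow-fibre muscle from the genotype, so it stays open. The slow-fibre mean was -0.56 in control replicate 2 and 0.22 to 0.89 in the YY1bKO arrays. A separate labelling batch, an infection of some animals, activation of resident cells without a change in their number, and the genotype stay open as well, and none of these 4 was tested.

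Slow-fibre muscle genes were higher in YY1bKO tissue, with 8 of 11 called and a median of 1.27, while 0 of 14 fast-fibre genes were called by limma. More muscle tissue of one kind in the YY1bKO pieces would raise both. Relative to control replicates 1 and 3 it did, since the slow minus fast difference of the YY1bKO arrays differed from theirs by -0.131. Control replicate 2 alone parts the lists, with fast-fibre transcripts above every YY1bKO array by 1.30 and slow-fibre transcripts below every one by 0.786. In 8 of 11 slow-fibre genes all YY1bKO arrays lay above all controls, as muscle of a different fibre type in the dissected pieces would also give, so more muscle, another fibre type and expression of these genes by the fat itself cannot be told apart.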

How the results depend on the processing

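The test with the muscle score was chosen after the data had been seen, and the others were planned. Yy1 kept its fall and its call in each alternative fit of genes, with log2 fold changes of -1.53 to -1.004, while with every probe set in place of genes the dimmest of its 4 was not called. With each array left out in turn, 547 to 1661 genes were higher and 466 to 1439 lower, the highest without control replicate 2. A fold of at least 1.5 left 469 higher and 562 lower, every probe set in place of genes gave 1997 and 1619, and the muscle score as a covariate gave 1786 and 1770. The arrays gave no clear sign that replicate numbers pair the samples. Deviations from the group means correlated at -0.25, 0.11 and 0.26 for replicates 1, 2 and 3. Control replicate 3 correlated best with YY1bKO replicate 3, and YY1bKO replicate 2 with control replicate 2, but the other arrays did not match their own number. So few correlations, with control replicate 2 set apart from the other arrays, cannot exclude a pairing. With the replicate block, 671 genes were higher and 639 lower, with 5 lists higher, the p53 and skeletal muscle lists among them, and the fibroblast list lower (adjusted p = 0.0461, 0.0362 and 0.0460). No called gene became called in the opposite direction under any of these fits, and 6 took the opposite sign without a call in the mean of all probe sets. Camera with an estimated correlation called 0 lists higher and 0 lower, so all 9 called lists lost their call there, and fry called 3 lower. Of the lists called by camera, fry did not call tricarboxylic acid cycle, fatty acid oxidation, extracellular matrix or endoplasmic reticulum unfolded protein response. Among the 176 named genes, 59 lost their call in at least 1 setting, mostly with an array left out. Not all of the 176 were called in the main fit, so the share of called genes that lost a call was larger. A call was gained by 27 in at least 1 setting, most often with array weights. At the preset correlation, 3 of the 9 called lists lost their call (fatty acid oxidation, extracellular matrix, endoplasmic reticulum unfolded protein response). A call was gained by 12 other lists. The medians of 17 lists, none of them called in the main fit, took the opposite sign in at least 1 setting, the smooth muscle and pericyte list with 0.26 without control replicate 2 among them. Among named genes signs turned for Kif11 (-0.0206 in the mean of its probe sets, which disagree), and for the uncalled neighbours of Ucp1, Mgat4d (0.0793 in the mean of its probe sets) and Zfp330 (0.0352 after quantile normalization, 0.0102 with array weights, -0.0354 to 0.0300 with an array left out). The skeletal muscle list had a median of -0.35 with the muscle score as a covariate, by construction of that score. Elsewhere the cause was not tested. The table gives no background level, so signal over background was not assessed, and 446 called genes lay at or below the median of all probe sets.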

Other observations

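Some further fixed lists belong to no comparison described so far. Of 28 peroxisome genes, 6 were lower and 2 higher, and 8 and 2 when adjusted over the list alone (camera adjusted p = 0.0872). The peroxisome set passed as lower without control replicate 2 (adjusted p = 0.00324), without YY1bKO replicate 1 (0.0496) and with array weights (0.0306). Phyh, the hydroxylase that starts the breakdown of phytanic acid, fell by 1.01 ± 0.11 (SE), and Pex19, a chaperone for peroxisomal membrane proteins, by 0.97 ± 0.13. Acaa1b, a peroxisomal thiolase, rose by 1.02 ± 0.15 and the coenzyme A hydrolase gene Nudt19 by 0.50 ± 0.07. Of 16 circadian clock genes, 2 were lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.865, with a positive median beside a negative mean). The output gene Hlf was 2.83-fold lower (adjusted p = 0.015) and Cry2 fell by 0.58 ± 0.15, while Clock rose by 0.43 ± 0.10, with its 2 probe sets in disagreement (0.18 in their mean, adjusted p = 0.195), and each of these 3 calls was lost when YY1bKO replicate 1, and again when YY1bKO replicate 2, was left out. Of 21 immediate early genes, 4 were lower and 0 higher, also when adjusted over the list alone (camera adjusted p = 0.107). This set passed as lower without control replicate 3 (adjusted p = 0.0400) or YY1bKO replicate 1 (0.0163). Jun fell by 0.89 ± 0.14 and Ier3 by 1.35 ± 0.30, and the Ier3 call was lost without control replicate 1, control replicate 3, YY1bKO replicate 1 or YY1bKO replicate 3. Among the 3 measured neighbours of Ucp1, where a Ucp1Cre transgene built from that region can carry extra gene copies, limma called 0 genes, also at an unadjusted p under 0.05 and when adjusted over the list alone, with changes of -0.10 for Clgn and -0.05 for Mgat4d, both dim, and -0.004 for Zfp330.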
